A study of Mus musculus with 12 samples.

How the data were processed

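The data were single-channel microarray values of 12 samples of mouse primary macrophages, 3 each of WT macrophages, WT TAMs, KO macrophages and KO TAMs, where KO stands for the Cd36 knockout and TAMs had been cultured for 72 h with the myeloma line 5TGM1. Per the labels' protocols, cells were grown in RPMI medium with serum and antibiotics, total RNA was isolated with a silica column kit, and cDNA was labelled with biotin using a whole-transcript kit for GeneChip arrays. The group and replicate number of each sample came from its title, and its genotype matched its characteristics. A time in culture was recorded for TAMs and not for macrophages, so co-culture differences may include time in culture. How the myeloma cells were removed from the cultures, whether replicates came from separate animals or cultures, and the sex of the animals are not given in the sources used here. The p-values therefore measure only the spread between these samples, which may be technical.

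The authors deposited 1 table of intensity values with a row per probe set and a column per array, which RMA had produced per the submitters' processing notes. RMA corrects the background, normalizes the arrays to a common distribution by quantiles and summarises the probes of a probe set, so that differences in overall brightness between arrays have been removed and changes shared by most genes cannot be seen. The deposited intensity values were on a linear scale, judged from their range, which began at 3.57, and their log2 was taken without a pseudocount. No value was missing. The submitters' processing notes also name limma, and give no version of either tool. A genome build is not given in the sources used here.

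The table held 41345 probe sets. By the array's annotation, 23521 of these had 1 gene symbol, 1814 had several and 16010 had none. Probe sets with several symbols or none were left out of the comparisons and named nowhere. Gene symbols were set against a RefSeq table of assembly GRCm38.p6 through the Entrez gene identifier, which 23325 probe sets shared with it, and 0 symbols changed. That table also gave the chromosome of genes and which genes neighbour Cd36. Where a gene had several probe sets (1082 genes), the probe set with the highest mean over the 12 arrays was kept, which left 22180 genes. No filter on level was applied. The array-wide median intensity lay between 31.3 and 33.3, and the group medians of the SD over genes were 0.096 in WT macrophages, 0.14 in WT TAMs, 0.105 in KO macrophages and 0.144 in KO TAMs. Levels thus varied more between TAM arrays, and how much of this was technical was not tested.

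Differences were estimated with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings on a design of 4 group means without covariates, so that all 12 arrays gave 1 estimate of the spread per gene with 8 residual degrees of freedom. TAM arrays varied more than macrophage arrays. This common spread can therefore make p too small between TAM groups and too large between macrophage groups. The comparisons were WT TAM against WT macrophage, KO TAM against KO macrophage, KO against WT macrophage, KO TAM against WT TAM, and the interaction, which is the KO minus the WT co-culture difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes. For Cd36 a two-sided exact permutation test of 3 against 3 arrays was added. Correlations across genes are descriptive, since genes are not independent replicates.

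Gene lists for lipid metabolism, macrophage activation, antigen presentation, cell growth, stress and other cell types the cultures could hold were written from textbook knowledge. There were 31 lists with 886 members, of which 799 were measured. Each of 29 lists was tested with camera against the other genes, with the correlation between genes preset at 0.01 and p adjusted over the 29 lists, and the sex-linked genes and the neighbours of Cd36 were given as values. Beside each called list stand the number of its genes called over all genes and that adjusted over the list alone, and the p with the correlation estimated per list, under which 2 of the 64 list calls held. In each called list the median, the mean and the direction of the test had 1 sign. Members are shared between lists in part.

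Genes were named by a rule. It took, per comparison, the 8 largest rises and 8 largest falls among called genes whose groups of arrays did not overlap (predicted, small RNA, olfactory and immunoglobulin genes left out), up to 4 members of each list that was called or described, and a fixed set of macrophage genes. With the few genes named after their values were seen, it gave 713 pairs of gene and comparison, 447 of them called. Of those, 300 kept their call when each array of the comparison was left out in turn and 147 did not. The text mainly gives genes of the first kind, a choice made after seeing the data, and names the arrays that ended a call for the others. Spp1, a macrophage gene of the lists, was not among the tested genes.

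The groups, the comparisons, the tests, the lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The alternatives were leaving out each array, fitting only the 6 arrays compared, quantile normalization applied again, centring each array on its median, leaving out dim genes under the 30th percentile of level, eBayes with trend and robust, array weights, the mean of a gene's probe sets, a minimum difference of 2-fold, the replicate number as a block, and for lists fry and camera with an estimated correlation. Testing all probe sets was also planned, and its counts are not given here. A further 2 alternatives were chosen after seeing the data. They left out WT TAM 2 and KO TAM 1, which lay apart from their groups, or added the mean of 14 stromal markers as a covariate.

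The steps were tested on simulated data with 200 changed genes in each comparison of the 22180 genes. At true log2 differences of 0.5, 1 and 2 the fit called 35.8, 88.1 and 98.5 percent of changed genes for WT TAM against WT macrophage, 32.8, 89.6 and 95.5 percent for KO TAM against KO macrophage, 44.8, 86.6 and 100 percent for KO against WT macrophage, 40.3, 85.1 and 97 percent for KO against WT TAM, and 9, 53.7 and 95.5 percent for the interaction, none with the wrong sign. False calls numbered 8, 7, 5, 2 and 5. The simulated noise was independent between genes, with 1 SD per gene for all groups. It left out the larger spread of TAM arrays, arrays that lay apart and correlation between genes. These rates may therefore not hold for the real arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and drew figures, and statmod 1.5.0 was used by limma.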

Results

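Gene expression was measured on 12 single-channel microarrays of mouse primary macrophages, in 4 groups of 3 arrays. The groups combined the genotype of the cells, wild type (WT) or knocked out (KO) for Cd36, with their culture. Cd36 encodes a scavenger receptor that takes up long-chain fatty acids and oxidised lipoproteins. Cells cultured alone are called macrophages here. Cells cultured for 72 h with 5TGM1 cells, a mouse multiple myeloma line, are called tumour-associated macrophages (TAMs). No time in culture was recorded for the cells cultured alone, so what is called a co-culture difference may include time in culture. The design addressed how macrophages and TAMs of each genotype differ in gene expression. Each array gave intensities for 41345 probe sets, with array medians between 31.3 and 33.3, from which 22180 genes were tested. The number of arrays limits the precision.

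All differences are on the log2 scale and, where an error follows, are given ± the standard error of the limma fit, with n = 3 arrays per group. Group levels are given ± SD over 3 arrays. A gene rose, fell or was called where its limma p, adjusted by the Benjamini-Hochberg method over the 22180 genes, was under 0.05. The macrophage genes Adgre1 (F4/80) and Cd68 were abundant on all 12 arrays, at 12.16 to 12.83 and 12.05 to 13.07, against a median of 5.34 over the mean levels of all tested genes. The plasma cell genes Jchain (3.28 to 3.84), Tnfrsf17 (3.35 to 4.09), Pou2af1 (4.17 to 4.66) and Mzb1 (5.06 to 5.49) had low levels on all 12 arrays, those with myeloma cells in the culture included, although the median level of the 30 myeloma and plasma cell markers was 6.49 on WT TAM 2 and 5.61 to 5.95 on the other arrays. Across genes, arrays of one group correlated at 0.996 to 0.997 in WT macrophages, 0.988 to 0.995 in WT TAMs, 0.995 to 0.996 in KO macrophages and 0.982 to 0.994 in KO TAMs, and arrays of different groups at 0.963 to 0.99. The first principal component held 47.7% of the variance. On it WT TAMs lay at 43 to 44.1, WT macrophages at -0.06 to 2.33 and KO macrophages at -39.1 to -38.8, whereas the KO TAMs were spread over 19.3, -11.6 and -23.7 for arrays 1, 2 and 3. KO TAM 1 lay more than 1 from the mean of KO TAM 2 and 3 in 550 genes, and WT TAM 2 from that of WT TAM 1 and 3 in 414.

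Cd36, the targeted gene, was read by 1 probe set and was lower on every KO array than on every WT array. In macrophages its level was 12.13 ± 0.03 in WT and 8.73 ± 0.09 in KO (difference -3.39 ± 0.24, 10.5-fold lower, adjusted p = 2e-05), and in TAMs 12.32 ± 0.20 and 8.92 ± 0.65 (-3.41 ± 0.24, 10.6-fold lower, adjusted p = 2.4e-05). The two-sided exact permutation p was 0.1 for each genotype comparison, the smallest that 3 against 3 arrays can give. The KO level was 9.5 percent of the WT intensity in macrophages and 9.4 percent in TAMs, and KO TAM 2 read 9.66 where KO TAM 1 and 3 read 8.45 and 8.64. All KO arrays thus read Cd36 above the 3.05 to 4.10 of the Y-linked genes Uty, Eif2s3y and Kdm5d on WT arrays, taken as background below. Whether the signal left is transcript or a higher background of this probe set was not tested. Which part of the transcript the probe set reads is not given in the sources used here. Co-culture did not change Cd36 detectably, with 0.19 in WT (adjusted p = 0.71) and 0.18 in KO (adjusted p = 0.75).

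The KO and WT arrays also differed in sex-linked genes, and the labels give no sex. Xist, the noncoding RNA of the inactive X chromosome, read 11.08 to 11.32 on the 6 WT arrays and 3.91 to 4.35 on the 6 KO arrays. The Y-linked genes Uty (6.57 ± 0.15), Eif2s3y (5.80) and Kdm5d (4.97) were higher in KO than in WT macrophages, and Uty (6.25), Eif2s3y (5.54) and Kdm5d (4.73) were higher in KO than in WT TAMs. These were the 3 called in macrophages among 17 Y-linked genes tested, and Usp9y (3.22 to 3.49) and Zfy2 (2.88 to 3.87) had low levels on all 12 arrays. Each genotype difference reported is therefore also a difference between arrays with an XX and with an XY expression pattern, and the data cannot separate the genotype from it. Of 899 X-linked genes tested, 109 differed between KO and WT macrophages (12.1%), against 11.3% of autosomal genes. Among the 40 tested genes nearest to Cd36 in the order of the GRCm38.p6 annotation, 4 differed in macrophages, Gsap (-0.85), Napepld (-0.82), Cacna2d1 (-0.79) and Gnai1 (-0.55), and 3 in TAMs, Gsap (-0.51), Fgl2 (1.15) and Phtf2 (0.72). Gnai1 was named after its value was seen. The calls of Cacna2d1 (adjusted p up to 0.0716 without WT macrophage 1 or KO macrophage 1), Gnai1 (up to 0.165 without any of WT macrophage 1, 2 and 3 and KO macrophage 1 and 2) and Phtf2 (up to 0.0595 without WT TAM 3, KO TAM 2 or KO TAM 3) were lost without single arrays.

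**Figure D1:**
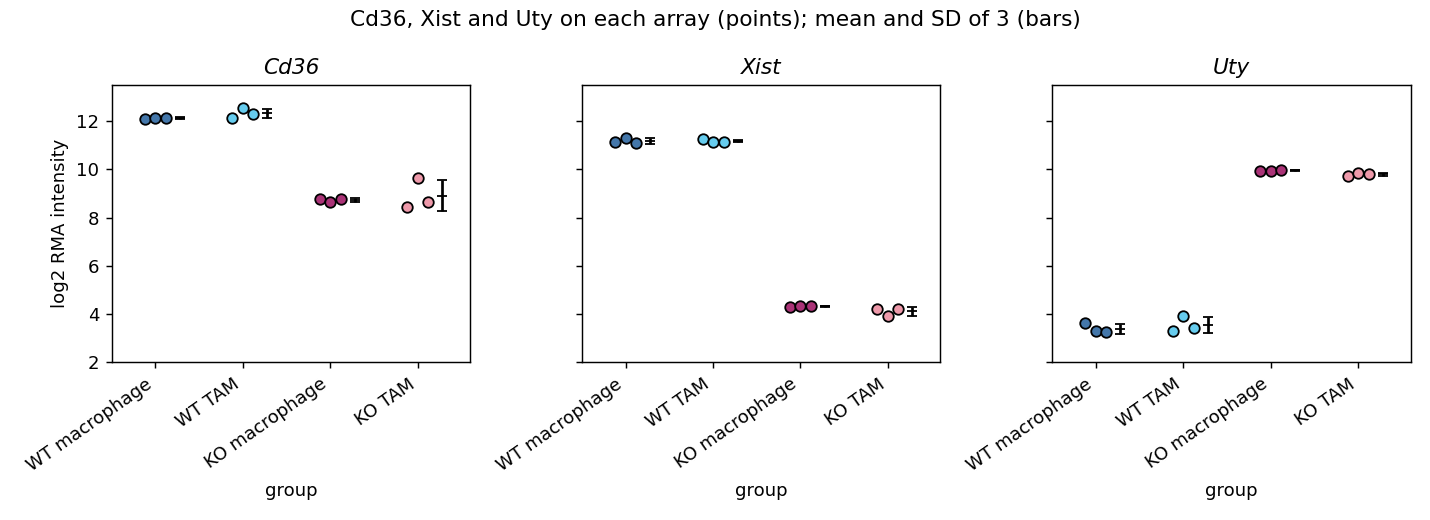
Level of Cd36, Xist and Uty (log2 intensity) on each of the 12 arrays, 1 point per array, by group. Cd36 lay at 12.13 ± 0.03 in WT and 8.73 ± 0.09 in KO macrophages (SD, n = 3 arrays), and the same 6 KO arrays that read Cd36 low read Xist at 3.91 to 4.35 and Uty high.

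Fabp4, Slc40a1 and 5 chemokines were higher in WT TAMs than in WT macrophages. Fabp4, a fatty acid binding protein, rose 15.7-fold (3.97 ± 0.86, adjusted p = 0.011), from 6.74 ± 0.11 to 10.72 ± 0.95, and Fabp5 rose by 2.29 ± 0.36. Slc40a1, the iron exporter ferroportin, rose 9-fold (3.17 ± 0.26, adjusted p = 3.4e-05), as did Rragd (3.17 ± 0.22), a GTPase of amino acid sensing. The chemokines Ccl12 (3.14 ± 0.35), Pf4 (3.07 ± 0.63), Ccl8 (3.0 ± 0.53), Ccl6 (2.97 ± 0.20) and Ccl7 (2.62) rose, and the mannose receptor Mrc1 rose by 1.98 ± 0.27, 3.93-fold (adjusted p = 0.0007). Il1b, which encodes interleukin-1 beta, fell by 1.86 ± 0.34 (adjusted p = 0.0039), and the gelatinase Mmp9 fell by 3.13.

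Other large falls in WT TAMs were those of Raver2 (-4.67 ± 0.95, 25.4-fold, adjusted p = 0.0078), Gpr18 (-4.27 ± 0.61), the Ras activator Rasgrp1 (-4.25 ± 0.54), Cd300e (-4.24 ± 0.82), Sez6l2 (-4.20 ± 0.57) and the integrin Itgal (-4.01 ± 0.85). The lectin Clec4a4 (-2.55), the calcium-binding protein Aif1 (-2.07), the transcription factors Batf3 (-1.45) and Spi1 (-0.81), and Nfkbiz (-1.63), a regulator of NF-kappaB, also fell, while Tgm2 (1.75), Mertk (1.08), a receptor for apoptotic cells, and the fatty acid transporter Slc27a1 (0.88) rose. Arg1 (0.47), Nos2 (0.26), Tnf (-1.07), Vegfa (1.16), Pparg (0.05) and Abca1 (0.23) did not pass the test. The lipid droplet coat gene Plin2 rose by 1.08 ± 0.24, a call lost without WT macrophage 1 (adjusted p = 0.0525).

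Gene groups of tumour-associated macrophages, lysosomes and matrix shifted up in WT TAMs. Among 34 measured tumour-associated macrophage markers, 17 rose and 4 fell (20 and 4 adjusted over the list alone), with a median of 0.78, camera adjusted p = 3.29e-09 and adjusted p = 0.203 with an estimated correlation. Havcr2 (1.58), Mif (1.22) and Ctsd (0.80) were among the genes called. The lysosome and phagocytosis list had 36 measured genes, 22 up and 3 down (25 and 5 adjusted over the list alone), with camera adjusted p = 3.29e-09 and adjusted p = 0.262 with an estimated correlation. The cholesterol exporters Npc1 (1.27) and Npc2 (0.65), the sialidase Neu1 (0.76) and Cd68 (0.81) were among them. In the extracellular matrix and angiogenesis list 12 of 38 rose and 1 fell (17 and 1 adjusted over the list alone), with camera adjusted p = 3.48e-07 and adjusted p = 0.41 with an estimated correlation. The protease Plau (2.13), Mmp13 (1.31), Vegfb (1.17) and Timp2 (1.10) passed the test. Glycolysis and hypoxia genes rose in 10 and fell in 3 of 34 cases (15 and 3 adjusted over the list alone), with camera adjusted p = 0.000117 and adjusted p = 0.291 with an estimated correlation. Tpi1 (0.65) and Pgam1 (0.64) of glycolysis and the collagen prolyl hydroxylase subunits P4ha2 (1.43) and P4ha1 (0.95) were among the members called.

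A further 6 lists were called in WT TAMs. PPAR and LXR targets rose in 5 and fell in 2 of 21 cases (5 and 2 adjusted over the list alone), with camera adjusted p = 0.00665 and adjusted p = 0.41 with an estimated correlation. Apoe (0.86) and Rxra (0.43) were among those that rose. NRF2 targets, genes of the response to oxidative stress, rose in 8 and fell in 1 of 27 cases (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0179 and adjusted p = 0.67 with an estimated correlation. Slc40a1, Mgst1 (1.05) and Gstm1 (0.61) were among the genes called. WT TAM 2 carried this shift, with a list mean of 9.97 against 9.19 and 9.29 on WT TAM 1 and 3 and 9.24 to 9.30 on WT macrophage arrays. Fibroblast, stromal and endothelial markers rose in 5 and fell in 1 of 28 cases (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0236 and adjusted p = 0.429 with an estimated correlation. The receptor Kdr (2.0) rose and the adhesion molecule Pecam1 (-2.38) fell. The 14 stromal genes of that list had a median of 0.96, and their mean was highest on WT TAM 2 (9.16, against 8.04 and 8.18 on WT TAM 1 and 3). The proliferation list shifted up by a median of 0.29 (camera adjusted p = 0.00252, adjusted p = 0.716 with an estimated correlation), though 2 of 43 genes passed (0 adjusted over the list alone). WT TAM 2 went the other way, with a list mean of 8.09 against 8.81 and 9.04 on WT TAM 1 and 3 and 8.35 to 8.40 on WT macrophage arrays. The genes called were Pcna (0.42) and Mcm2 (0.67), whose calls were lost without any of WT macrophage 1, 2 and 3 and WT TAM 1 and 3 (adjusted p up to 0.0945 and 0.122). Osteoclast markers rose in 3 and fell in 7 of 19 cases (4 and 9 adjusted over the list alone), with camera adjusted p = 0.00711 and adjusted p = 0.33 with an estimated correlation. The fusion protein Dcstamp (-1.34) and the RANK receptor Tnfrsf11a (-0.92) passed the test. B cell markers fell in 4 of 16 cases (4 adjusted over the list alone), with camera adjusted p = 0.0282 and adjusted p = 0.352 with an estimated correlation. The adaptor Blnk (-0.60) was among them. List calls were lost without WT TAM 2 for PPAR and LXR targets (adjusted p = 0.0956), NRF2 targets (0.656) and stromal markers (0.134), without WT TAM 3 for proliferation (0.381) and B cell markers (0.0604), and without WT TAM 1 for B cell markers (0.056).

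Lipid uptake and storage genes went both ways in WT TAMs, 9 up and 3 down of 32 (12 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0674). The myeloma and plasma cell markers did not pass either, 2 up and 5 down of 30 (2 and 6 adjusted over the list alone; camera adjusted p = 0.636). In all, 2561 genes were called in WT TAMs against WT macrophages, 1306 higher and 1255 lower. Lower genes were the majority when quantile normalization was applied again (1189 higher and 1366 lower) or arrays were centred on their medians (1115 and 1302). In 30.1% of all genes the groups did not overlap, against 10% by chance. Without 1 array the count was 1475, 1619 or 1514 (without WT macrophage 1, 2 or 3), and it was 4049 without WT TAM 2 and KO TAM 1, which lay apart from their groups, 3976 with array weights, and 1142 with the stromal marker mean as a covariate. Leaving out these arrays and the covariate were chosen after the results were seen. List calls were gained without WT TAM 1 for lipid uptake (0.0281) and MHC class I (0.0395) and without WT TAM 2 for cholesterol synthesis (0.000769). Over the 12 alternatives of each called list the p with an estimated correlation was the highest, except for stromal markers (0.755 with the stromal marker mean as a covariate) and NRF2 targets (0.879 without WT TAM 2 and KO TAM 1), and the lowest lay between 2.77e-13 (proliferation) and 0.00958 (B cell markers).

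In KO cells too, Ccl8, Fabp4 and Slc40a1 were higher in TAMs than in macrophages. Ccl8 rose 26.8-fold (4.75 ± 0.53, adjusted p = 0.00051), from 5.48 ± 0.06 to 10.23 ± 0.86. Slc40a1 rose by 3.41 ± 0.26 (adjusted p = 4.3e-05), the interleukin-7 receptor Il7r by 3.37 ± 0.37, the interferon-induced Ifi205 by 3.32 ± 0.33, Pf4 by 3.32 ± 0.63, the endothelin receptor Ednrb by 3.61 ± 0.59 and Fabp5 by 3.23 ± 0.36. Fabp4 rose (4.30 ± 0.86, adjusted p = 0.013) from a low level of 4.10 to 5.29 on KO macrophage arrays to 11.63, 8.09 and 7.29 on KO TAM 1, 2 and 3. Its call was lost without KO macrophage 1 (adjusted p = 0.0585). Cmah (-2.38 ± 0.25, adjusted p = 0.00033), an enzyme of sialic acid metabolism, Fam71a (-2.36 ± 0.28) and Garnl3 (-2.05 ± 0.17) fell.

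The receptors Clec7a (dectin-1, 2.29), Msr1 (2.06) and Mrc1 (1.59 ± 0.27) rose in KO TAMs, as did the vacuolar ATPase subunit Atp6v0d2 (2.92). The growth factor Vegfa (2.17 ± 0.39) and Cpt1a (1.24 ± 0.16), which takes fatty acids into mitochondria, rose as well. Plin2 rose by 1.23, a call lost without KO macrophage 2 (adjusted p = 0.0517).

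Tumour-associated macrophage markers had the smallest list p in KO TAMs, with 19 of 34 up and 0 down (25 and 0 adjusted over the list alone) and a median of 0.79. They included Axl (1.79), Gpnmb (1.78), Folr2 (1.72) and Lgals3 (1.48), with camera adjusted p = 7.74e-21 and adjusted p = 0.0177 with an estimated correlation. Lysosome and phagocytosis genes rose in 18 and fell in 2 of 36 cases (23 and 2 adjusted over the list alone), with camera adjusted p = 8.01e-13 and adjusted p = 0.0524 with an estimated correlation. The Fc receptor Fcgr2b (1.77), Cd68 (0.83) and Npc2 (0.52) rose, and the integrin Itgb2 (-0.63) fell. MHC class I presentation genes rose in 9 of 19 cases (10 adjusted over the list alone), with camera adjusted p = 1.45e-10 and adjusted p = 0.0524 with an estimated correlation. H2-K1 (1.16), H2-T23 (1.15), Tapbp (0.88) and H2-M3 (0.87) were among the genes called. Among MHC class II presentation genes 4 of 13 rose (7 adjusted over the list alone), with camera adjusted p = 3.32e-05 and adjusted p = 0.129 with an estimated correlation. The lysosomal thiol reductase Ifi30 (1.55) and the protease Lgmn (0.47) were among them. The type I interferon list shifted up by a median of 0.46 with 3 of 31 genes called (3 adjusted over the list alone), with camera adjusted p = 1.22e-06 and adjusted p = 0.505 with an estimated correlation. Ifitm3 (1.55) and Oasl2 (0.94) passed the test. KO TAM 2 and 3 carried this shift, since the mean of the list was 8.96, 9.01 and 8.99 on KO macrophage 1, 2 and 3 and 8.71, 9.75 and 10.01 on KO TAM 1, 2 and 3.

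Inflammatory, oxidative stress and matrix lists rose too in KO TAMs. Neutrophil chemokines and inflammatory mediators rose in 6 and fell in 1 of 31 cases (9 and 1 adjusted over the list alone), with camera adjusted p = 5.33e-06 and adjusted p = 0.0524 with an estimated correlation. The acute phase protein Saa3 (2.0), Clec4d (1.65) and the adhesion molecule Vcam1 (1.54) were among the members called. Matrix and angiogenesis genes rose in 11 of 38 cases (15 up and 1 down adjusted over the list alone), with camera adjusted p = 1.08e-08 and adjusted p = 0.223 with an estimated correlation. Vegfa, Plaur (1.42), Plau (1.19) and Timp2 (1.05) were called. NRF2 targets rose in 7 of 27 cases (11 up and 1 down adjusted over the list alone), with camera adjusted p = 5.71e-07 and adjusted p = 0.287 with an estimated correlation. Mgst1 (1.38), the haem transporter Slc48a1 (0.80) and Txn1 (0.68) were among the genes called. Fibroblast, stromal and endothelial markers, with the proteoglycans Bgn (2.49) and Dcn (1.77), rose in 4 and fell in 1 of 28 cases (8 and 1 adjusted over the list alone), camera adjusted p = 0.000182 and adjusted p = 0.167 with an estimated correlation. Their 14 stromal genes had a median of 1.32. Macrophage identity genes rose in 8 and fell in 2 of 29 cases (14 and 4 adjusted over the list alone), with camera adjusted p = 0.00126 and adjusted p = 0.0524 with an estimated correlation. The Fc receptors Fcgr1 (1.40) and Fcgr3 (1.05) rose and the transcription factor Spi1 (-0.48) fell.

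Further lists called in KO TAMs included 3 of lipid metabolism. PPAR and LXR targets rose in 8 of 21 cases (8 up and 2 down adjusted over the list alone), with camera adjusted p = 1.52e-05 and adjusted p = 0.145 with an estimated correlation. Cpt1a, the lipoprotein component Apoc2 (1.23) and Abhd4 (0.65) passed the test. Lipid uptake and storage genes rose in 7 and fell in 2 of 32 cases (7 and 2 adjusted over the list alone), with camera adjusted p = 0.00499 and adjusted p = 0.0524 with an estimated correlation. Fabp5, Msr1, Slc27a1 (0.70) and Plin3 (0.53) were among the members called. Fatty acid oxidation genes rose in 3 of 25 cases (3 adjusted over the list alone), with camera adjusted p = 0.0101 and adjusted p = 0.392 with an estimated correlation. Cpt1a was among them. Of 34 glycolysis and hypoxia genes 2 rose, among them P4ha1 (0.74), and 1 fell, Ddit4 (-1.08), an inhibitor of mTOR signalling (5 and 2 adjusted over the list alone), with camera adjusted p = 0.0484 and adjusted p = 0.439 with an estimated correlation. The proliferation list shifted down by a median of -0.32, with 2 of 43 genes lower, E2f8 (-0.94) and Rrm2 (-0.85) (2 adjusted over the list alone), camera adjusted p = 0.000116 and adjusted p = 0.637 with an estimated correlation. Their calls were lost without KO macrophage 2, KO macrophage 3 or KO TAM 3 (highest adjusted p = 0.103 and 0.0929), and that of Rrm2 also without KO macrophage 1 or KO TAM 1. M1-type activation genes did not pass (3 of 26 up, 7 up and 1 down adjusted over the list alone, camera adjusted p = 0.051), nor did M2-type genes (3 up and 1 down of 27, 7 and 2 adjusted over the list alone, camera adjusted p = 0.323), whose median of -0.01 and mean of 0.15 differed in sign. List calls were lost for glycolysis and hypoxia without KO macrophage 1 (adjusted p = 0.0748), KO macrophage 3 (0.0685) or KO TAM 1 (0.262), for fatty acid oxidation without KO TAM 1 (0.144) and for proliferation without KO TAM 3 (0.0825).

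In KO cells 1449 genes were called, 643 higher and 806 lower in TAMs, and the groups did not overlap in 26.3% of all genes, against 10% by chance. The count was 647, 614 or 611 without KO macrophage 1, 2 or 3, 505 with only the 6 arrays compared, 2705 with array weights and 193 with the stromal marker mean as a covariate. List calls were gained for M1-type activation without KO macrophage 2 (0.0492) or KO TAM 1 (0.00525) and for cholesterol synthesis without KO TAM 2 (0.0323). Over the 12 alternatives of each called list the p with an estimated correlation was the highest, except with the stromal marker mean as a covariate for matrix (0.762), fatty acid oxidation (0.66), stromal (0.778), glycolysis (0.762) and lipid uptake (0.149) genes, and the lowest lay between 8.78e-24 (interferon) and 0.0146 (glycolysis).

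Genes that responded to co-culture moved mostly in the same direction in both genotypes. Across the 22180 genes the log2 differences of WT and KO cells, which share no array, correlated with Pearson r = 0.678 and Spearman rho = 0.466. Genes are not independent replicates, so no p is given. Called in both were 404 genes that rose, against 37.9 for independent lists, and 487 that fell, against 45.6. The calls of both comparisons rest on the same estimate of the spread per gene, which by itself can raise these overlaps. Of the 2561 genes called in WT, 2335 had the same sign in KO, and the slope of the KO on the WT differences over them was 0.613. By array it was 0.96 for KO TAM 1, 0.48 for KO TAM 2 and 0.4 for KO TAM 3. These genes were chosen by their WT call, which by itself lowers a KO slope. In contrast, 4 genes were called in opposite directions, Ankrd28 (0.70 in WT, -0.35 in KO), Gpr141 (-0.94, 0.89), Mir27a (0.60, -0.63) and Sccpdh (0.32, -0.39), named after their values were seen. The calls of Mir27a held without each array in turn. Those of Ankrd28 in KO (adjusted p up to 0.1 without KO macrophage 1, 2 or 3 or KO TAM 1), Gpr141 in WT (up to 0.0569 without WT macrophage 2, WT TAM 1 or WT TAM 3) and in KO (up to 0.0951 without any KO macrophage array) and Sccpdh in WT (up to 0.108 without any of the 6 arrays) and in KO (up to 0.0748 without KO macrophage 2 or 3) did not. The correlation fell to r = 0.532 without KO TAM 1. The numbers higher and lower in both were 244 and 305 without WT macrophage 1, 253 and 289 without WT macrophage 2, 243 and 299 without WT macrophage 3, 201 and 233 without KO macrophage 1, 199 and 219 without KO macrophage 2, and 215 and 216 without KO macrophage 3.

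**Figure D2:**
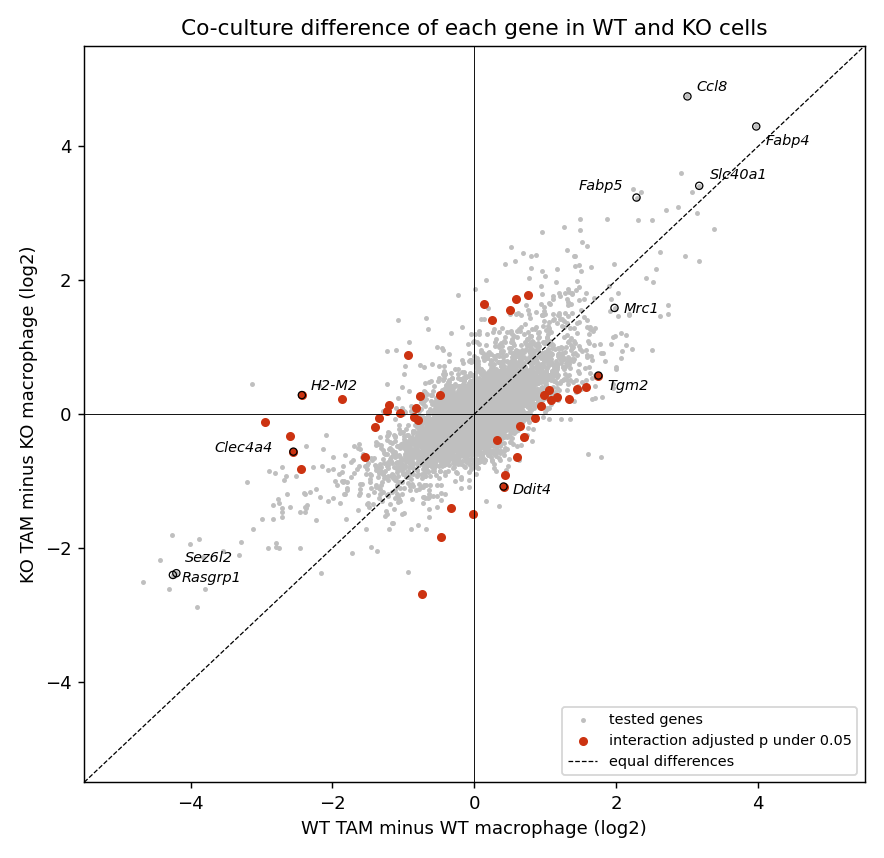
Co-culture effect in KO cells (KO TAM minus KO macrophage, log2) against that in WT cells (WT TAM minus WT macrophage, log2), 1 point per gene for the 22180 genes tested, with genes of the text named. Most points follow a rising diagonal (r = 0.678 across genes), and Fabp4 and Slc40a1 lie high on both axes.

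Between KO and WT macrophages cultured alone, Fn1 (fibronectin) was 20.3-fold lower (-4.35 ± 0.61, adjusted p = 0.0012), at 5.99 in KO against 10.34 in WT, Mmp9 differed by -4.22 ± 0.57 (adjusted p = 0.001), periostin (Postn) by -3.81 ± 0.65, biglycan (Bgn) by -3.80 ± 0.44 (adjusted p = 0.0004), Igfbp7 by -3.74 ± 0.52, S100a6 by -3.73 ± 0.46 and the MHC gene H2-M2 by -3.69 ± 0.21 (adjusted p = 4.1e-06). Higher in KO were the interferon-inducible GTPase Gbp8 (3.41 ± 0.69, adjusted p = 0.0083), the transporter Abcg3 (2.28 ± 0.33), the co-receptor Cd4 (2.14 ± 0.31) and Apoe (1.02). Cpt1a was lower (-1.56 ± 0.16, adjusted p = 0.00023), as were the growth factor Csf1 (-1.97), Mfge8 (-2.48), which bridges macrophages to apoptotic cells, the scavenger receptor Msr1 (-1.86), Il7r (-2.52), Clec7a (-1.48) and the malic enzyme Me1 (-1.34).

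Proliferation genes had the smallest list p, with 38 of 43 lower in KO macrophages (40 adjusted over the list alone), with a median of -1.18, camera adjusted p = 3.72e-32 and adjusted p = 0.147 with an estimated correlation. Ube2c (-2.09), E2f8 (-1.60), Cdc6 (-1.44) and Cdk1 (-1.15) were called. In the matrix and angiogenesis list 17 of 38 were lower and 2 higher (19 and 3 adjusted over the list alone), with camera adjusted p = 3.86e-10 and adjusted p = 0.173 with an estimated correlation. Sparc (-3.29), Col1a2 (-2.74) and Timp1 (-2.52) were among the genes called. Fibroblast, stromal and endothelial markers were lower in 10 of 28 cases (12 adjusted over the list alone), camera adjusted p = 2.28e-05 and adjusted p = 0.147 with an estimated correlation. The 14 stromal genes of that list had a median of -1.49 with 9 called lower, and its 11 endothelial genes a median of 0.03 with 0 called. The mean of the 14 stromal genes was 7.53 to 7.69 on the WT macrophage and 5.65 to 5.77 on the KO macrophage arrays, and the mean of the proliferation genes was 8.35 to 8.40 and 7.10 to 7.19. Tumour-associated macrophage markers were lower in 14 and higher in 4 of 34 cases (18 and 4 adjusted over the list alone), with camera adjusted p = 3.03e-06 and adjusted p = 0.147 with an estimated correlation. The collagen-degrading protease Ctsk (-3.19), Folr2 (-1.56), Axl (-1.44) and Gpnmb (-1.25) were among them. Osteoclast markers were lower in 8 of 19 cases (9 lower and 1 higher adjusted over the list alone), with camera adjusted p = 0.000118 and adjusted p = 0.147 with an estimated correlation. Ctsk, Dcstamp (-1.20) and the carbonic anhydrase Car2 (-0.85) passed the test.

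A further 8 lists were lower in KO macrophages. ER stress and amino acid response genes were lower in 10 and higher in 2 of 30 cases (11 and 2 adjusted over the list alone), with camera adjusted p = 1.36e-05 and adjusted p = 0.0903 with an estimated correlation. Psat1 (-1.52) and Shmt2 (-1.01) of serine metabolism were lower and the phosphatase subunit Ppp1r15a (0.69) was higher. Oxidative phosphorylation genes were lower in 11 and higher in 2 of 42 cases (15 and 3 adjusted over the list alone), with camera adjusted p = 2.67e-05 and adjusted p = 0.19 with an estimated correlation. Mdh2 (-0.52), Uqcrc1 (-0.51) and Cs (-0.50) were called. Fatty acid oxidation genes were lower in 5 of 25 cases (9 adjusted over the list alone), with camera adjusted p = 0.000118 and adjusted p = 0.173 with an estimated correlation. Cpt1a, Acads (-0.78) and the carnitine carrier Slc25a20 (-0.69) were among the genes called. Glycolysis and hypoxia genes were lower in 8 and higher in 3 of 34 cases (12 and 3 adjusted over the list alone), with camera adjusted p = 0.00182 and adjusted p = 0.2 with an estimated correlation. The glucose transporter Slc2a1 (-0.84) and Pfkp (-0.82) were lower and Ddit4 (1.06) was higher. Lipid uptake and storage genes were lower in 5 and higher in 1 of 32 cases (5 and 1 adjusted over the list alone), with camera adjusted p = 0.00229 and adjusted p = 0.0903 with an estimated correlation. Msr1, Slc27a1 (-0.97) and the lipase Lpl (-0.83) passed the test. NRF2 targets were lower in 6 of 27 cases (7 adjusted over the list alone), with camera adjusted p = 0.000265 and adjusted p = 0.424 with an estimated correlation. Nqo1 (-1.76) and Txn1 (-0.89) were among the members called. The chemokine and inflammatory list, with Csf1, Clec4d (-0.89) and Sod2 (-0.60), was lower in 6 of 31 cases (6 adjusted over the list alone), camera adjusted p = 0.000608 and adjusted p = 0.147 with an estimated correlation. Of 13 MHC class II presentation genes 3 were lower, Ifi30 (-1.11) among them (4 adjusted over the list alone), camera adjusted p = 0.0202 and adjusted p = 0.36 with an estimated correlation. The call of MHC class II was lost without WT macrophage 2 (adjusted p = 0.0629) or KO macrophage 1 (0.0581).

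**Figure D3:**
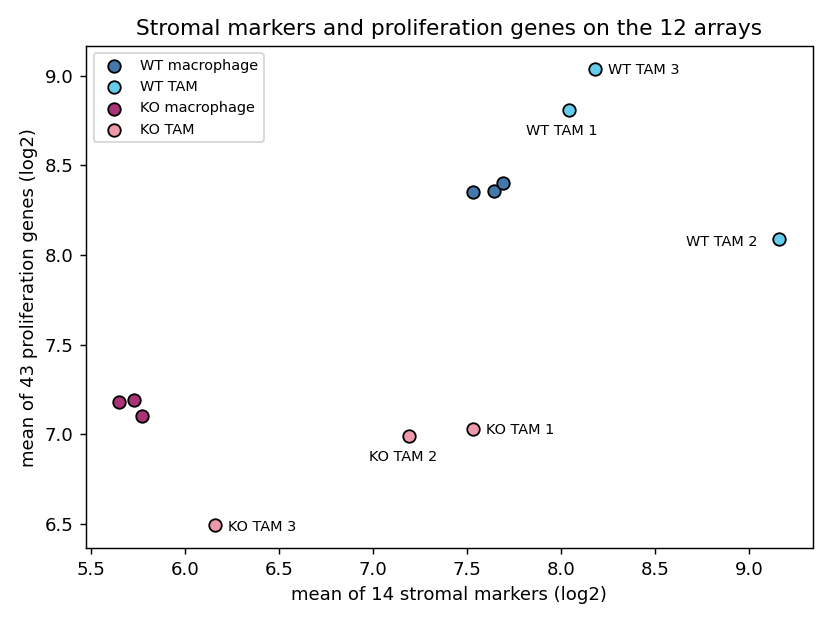
Mean level of the 43 proliferation genes (log2 intensity) against the mean level of the 14 stromal markers (log2 intensity), 1 point per array for 12 arrays, coloured by group. KO macrophage arrays lie at 5.65 to 5.77 for stromal markers and 7.10 to 7.19 for proliferation genes, WT macrophage arrays at 7.53 to 7.69 and 8.35 to 8.40.

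In macrophages 2512 genes differed between genotypes, 1152 higher and 1360 lower in KO, and of those at least 2-fold apart 59 were higher and 404 lower. Among all called genes the majority turned, to 1400 higher and 1282 lower with quantile normalization applied again and to 1251 and 1192 with arrays centred. The groups did not overlap in 38.5% of all genes, against 10% by chance. Without WT macrophage 1, 2 or 3 the count was 1414, 1434 or 1403, and without KO macrophage 1, 2 or 3 it was 1503, 1478 or 1465. It was 4558 without WT TAM 2 and KO TAM 1, 4716 with only the 6 arrays compared, 4923 with array weights and 190 with the stromal marker mean as a covariate. Over the 12 alternatives of each called list the p with an estimated correlation was the highest, except with the stromal marker mean as a covariate for matrix (0.94), fatty acid oxidation (0.479), stromal (0.772), glycolysis (0.785), lipid uptake (0.474), MHC class II (0.772), osteoclast (0.34) and NRF2 (0.969) genes, and the lowest lay between 5.75e-34 (proliferation) and 0.00207 (MHC class II).

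Between KO and WT TAMs, the elastase Mmp12 was among the genes that were lower in KO and Rasgrp1 among those that were higher. Mmp12 was 10.2-fold lower (-3.36 ± 0.64, adjusted p = 0.0054), and Postn (-2.98 ± 0.65), S100a6 (-2.75 ± 0.46), neuropeptide Y (Npy, -2.73 ± 0.33, adjusted p = 0.00039) and tenascin C (Tnc, -2.68 ± 0.50) were lower too. Rasgrp1 (2.77 ± 0.54), the transcription factor Spic (2.75 ± 0.49), Clec4a4 (2.56 ± 0.18, adjusted p = 2.4e-05), Calhm6 (2.30 ± 0.25) and Tmem176a (2.15 ± 0.45) were higher in KO. Cpt1a was lower (-0.92 ± 0.16, adjusted p = 0.0033) and Cd274, which encodes the checkpoint ligand PD-L1, was higher (0.82 ± 0.15, adjusted p = 0.0045). Interleukin-10 (Il10) was higher by 1.51 ± 0.33, a call lost without KO TAM 2 (adjusted p = 0.0527).

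Of 43 proliferation genes 42 were lower in KO TAMs (43 adjusted over the list alone), with a median of -1.90, camera adjusted p = 5.28e-46 and adjusted p = 0.104 with an estimated correlation. Rrm2 (-2.33), Mcm6 (-1.74), Cdk1 (-1.69) and Cdc45 (-1.52) were called. The mean of the list was 8.81, 8.09 and 9.04 on WT TAM 1, 2 and 3 and 7.03, 6.99 and 6.49 on KO TAM 1, 2 and 3. Matrix and angiogenesis genes were lower in 16 of 38 cases (21 adjusted over the list alone), with camera adjusted p = 3.14e-11 and adjusted p = 0.162 with an estimated correlation. Col1a2 (-2.39), Mmp13 (-1.74), Plau (-1.56) and Col6a1 (-1.48) were among the genes called. Fibroblast, stromal and endothelial markers were lower in 12 and higher in 1 of 28 cases (16 and 2 adjusted over the list alone), with camera adjusted p = 0.000249 and adjusted p = 0.162 with an estimated correlation. Col1a1 (-2.32) and the chemokine Cxcl12 (-1.95) were lower and the endothelial Pecam1 (1.71) was higher. The 14 stromal genes had a median of -1.68, and their mean was 8.04, 9.16 and 8.18 on WT TAM 1, 2 and 3 and 7.53, 7.19 and 6.16 on KO TAM 1, 2 and 3.

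Glycolysis and hypoxia genes were lower in 14 and higher in 2 of 34 cases in KO TAMs (19 and 3 adjusted over the list alone), with camera adjusted p = 3.63e-07 and adjusted p = 0.104 with an estimated correlation. Pfkp (-0.78), pyruvate kinase Pkm (-0.75), Pgk1 (-0.68) and Pgam1 (-0.58) passed the test. Oxidative phosphorylation genes were lower in 7 and higher in 1 of 42 cases (12 and 2 adjusted over the list alone), with camera adjusted p = 7.44e-05 and adjusted p = 0.244 with an estimated correlation. Mdh2 (-0.53), Idh2 (-0.52) and Cs (-0.38) were among the members called. ER stress and amino acid response genes were lower in 6 and higher in 1 of 30 cases (10 and 3 adjusted over the list alone), with camera adjusted p = 0.00109 and adjusted p = 0.104 with an estimated correlation. Psat1 (-1.32) and Shmt2 (-0.91) were lower and the chaperone Dnajb9 (0.60) was higher. Fatty acid oxidation genes were lower in 5 of 25 cases (7 adjusted over the list alone), with camera adjusted p = 0.00157 and adjusted p = 0.256 with an estimated correlation. Cpt1a and Hadh (-0.46) were among the genes called. Lipid uptake and storage genes were lower in 5 and higher in 1 of 32 cases (5 and 1 adjusted over the list alone), with camera adjusted p = 0.0289 and adjusted p = 0.119 with an estimated correlation. Slc27a1 (-1.15), Lpl (-0.84) and the receptor Lrp1 (-0.76) were among them, and the list call was lost without WT TAM 2 (adjusted p = 0.107) or KO TAM 2 (0.066). Tumour-associated macrophage markers were lower in 12 and higher in 5 of 34 cases (16 and 7 adjusted over the list alone), with camera adjusted p = 0.00304 and adjusted p = 0.256 with an estimated correlation. The chemokine Ccl2 (-1.47), Havcr2 (-1.30) and Mif (-0.78) were lower and the checkpoint protein Vsir (0.79) was higher.

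There were 5 lists with higher values in KO TAMs. Macrophage identity genes were higher in 10 of 29 cases (14 adjusted over the list alone), with camera adjusted p = 7.09e-05 and adjusted p = 0.0326 with an estimated correlation. Aif1 (1.61), Adgre4 (1.44), Tlr7 (0.64) and Cd200r1 (0.48) were among the members called. The type I interferon list shifted up by a median of 0.59, with 6 of 31 genes higher (9 adjusted over the list alone), with camera adjusted p = 9.22e-07 and adjusted p = 0.563 with an estimated correlation. The sensors and regulators Trim30a (0.77) and Ifih1 (0.76) were called. The mean level of the interferon list was 8.42, 9.19 and 8.95 on WT TAM 1, 2 and 3 and 8.71, 9.75 and 10.01 on KO TAM 1, 2 and 3. M1-type activation genes were higher in 5 of 26 cases (6 adjusted over the list alone), with camera adjusted p = 0.00146 and adjusted p = 0.119 with an estimated correlation. Il18 (0.69) was among them. MHC class I presentation genes were higher in 3 of 19 cases (3 adjusted over the list alone), with camera adjusted p = 0.00804 and adjusted p = 0.313 with an estimated correlation. H2-T23 (0.72) and H2-K1 (0.66) were among them, and the list call was lost without KO TAM 3 (adjusted p = 0.0615). Dendritic cell markers were higher in 3 and lower in 2 of 20 cases (3 and 2 adjusted over the list alone), with camera adjusted p = 0.019 and adjusted p = 0.119 with an estimated correlation. Clec4a2 (1.0) and the transcription factor Irf8 (0.66) passed the test. NRF2 targets, lower in 5 of 27 cases (5 adjusted over the list alone), did not pass (camera adjusted p = 0.0541). Nor did MHC class II presentation, higher in 1 of 13 cases (1 adjusted over the list alone, camera adjusted p = 0.25), or chemokines and inflammatory mediators, higher in 3 and lower in 2 of 31 cases (3 and 2 adjusted over the list alone, camera adjusted p = 0.739).

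**Figure D4:**
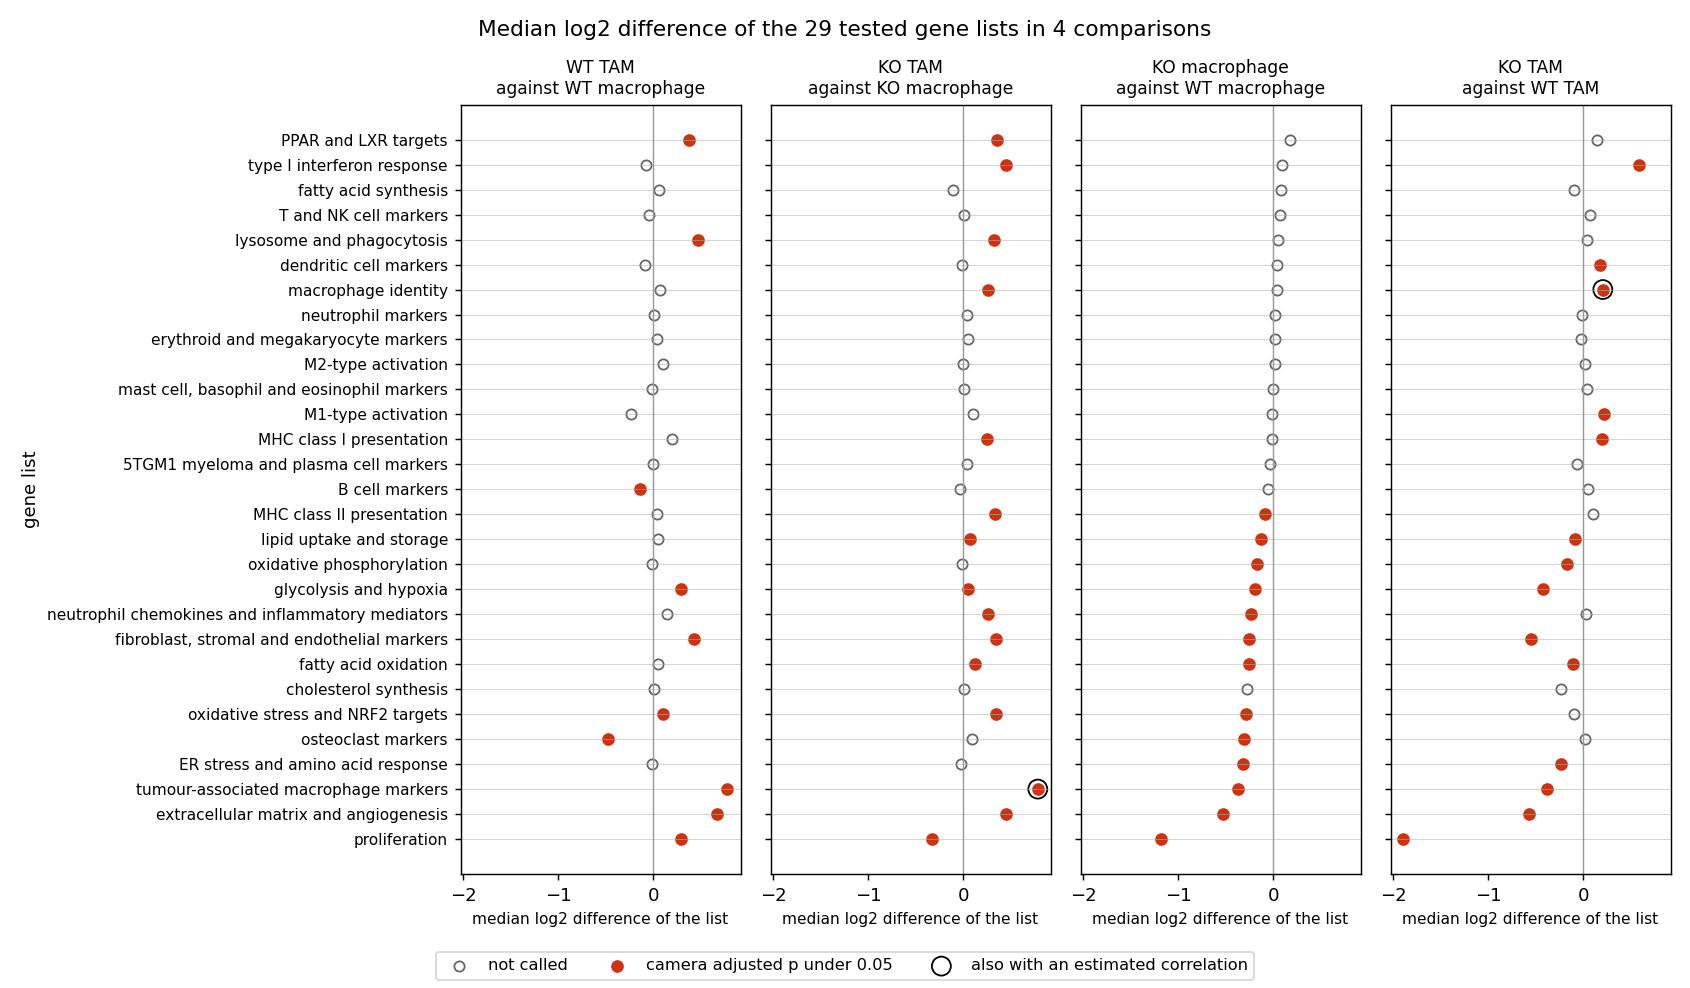
Median log2 difference of each tested gene list in 4 comparisons, 1 point per list and comparison, with filled points for lists whose camera adjusted p was under 0.05. The proliferation list lies lowest in both genotype comparisons, at -1.18 in macrophages and -1.90 in TAMs.

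In TAMs 2710 genes differed between genotypes, 1116 higher and 1594 lower in KO, with 98 higher and 535 lower among those at least 2-fold apart. Of the 2710, 2559 had groups of arrays that did not overlap. The spread of the fit came in part from macrophage arrays, which varied less, so p may be too small here. With quantile normalization applied again 1462 were higher and 1429 lower, and with arrays centred 1170 and 1437. The excess of lower genes among all called genes thus depended on which scaling was used. The groups did not overlap in 24.6% of all genes, against 10% by chance. The count was 1749 without KO TAM 2, 638 with only the 6 arrays compared, 4725 with array weights, 4480 without WT TAM 2 and KO TAM 1, and 526 with the stromal marker mean as a covariate. List calls were gained for NRF2 targets without WT TAM 1 (0.00219), WT TAM 3 (0.0074) or KO TAM 2 (0.0155), for cholesterol synthesis without WT TAM 2 (2.88e-06) or KO TAM 1 (0.00467), and without WT TAM 2 for fatty acid synthesis (0.00139) and PPAR and LXR targets (0.0109). Over the 12 alternatives of each called list the p with an estimated correlation was the highest, except for ER stress (0.156 without WT TAM 2 and KO TAM 1) and, with the stromal marker mean as a covariate, for matrix (0.266), fatty acid oxidation (0.522), stromal (0.563), lipid uptake (0.493), M1-type (0.266), MHC class I (0.94) and tumour-associated macrophage (0.542) genes, and the lowest lay between 5.48e-57 (proliferation) and 0.00336 (lipid uptake). The genotype differences in TAMs and in macrophages, which share no array, correlated across genes with r = 0.716 and rho = 0.517. Called in both were 458 higher genes (58 for independent lists) and 842 lower genes (97.7). The same estimate of the spread per gene serves both comparisons, which by itself can raise these overlaps.

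The response to co-culture differed between genotypes for 43 genes, 23 with a higher and 20 with a lower value in KO. H2-M2 fell by 2.43 in WT and differed by 0.28 in KO (interaction 2.72 ± 0.30, adjusted p = 0.0056), with levels of 8.86 and 6.43 in WT macrophages and TAMs and 5.18 and 5.46 in KO. Shisa3 fell by 2.60 in WT, against -0.33 in KO (2.28 ± 0.23, adjusted p = 0.0037). Its level went from 7.26 to 4.66 in WT and from 5.26 to 4.93 in KO. From the KO macrophage levels of H2-M2 and Shisa3, falls as large as in WT would end below the background. That lay near 3.05 to 4.10 for Uty, Eif2s3y and Kdm5d on WT arrays. Equal responses of H2-M2 and Shisa3 could therefore not have been read. The ubiquitin hydrolase Uchl1 (2.08 ± 0.20) and the lectin Clec4a4 (1.99 ± 0.25) also fell in WT without a called change in KO. The Fc receptor Fcgr1 differed by 0.25 in WT and rose by 1.40 in KO (1.16 ± 0.12, adjusted p = 0.0037), and the chemerin receptor Cmklr1 differed by 0.14 and rose by 1.65 (1.51 ± 0.18). The MHC-related Mr1 rose more in WT, with 1.58 in WT and 0.40 in KO (interaction -1.18 ± 0.15). The sialyltransferase St8sia6 fell more in KO, with -0.47 in WT and -1.83 in KO (interaction -1.36 ± 0.18). These 8 genes kept their call without each array in turn.

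Among the lists, 10 had a higher response in KO. The type I interferon list had an interaction median of 0.53 with 1 of 31 genes called (1 adjusted over the list alone), camera adjusted p = 4.19e-08 and adjusted p = 0.432 with an estimated correlation. KO TAM 2 and 3 carried the rise in KO cells, with list means of 9.75 and 10.01. KO TAM 1, at 8.71, lay below the KO macrophage arrays (8.96 to 9.01). MHC class I presentation had a median of 0.29 with 0 of 19 called (0 adjusted over the list alone), camera adjusted p = 9.9e-07 and adjusted p = 0.104 with an estimated correlation. MHC class II presentation had a median of 0.34 with 0 of 13 called (6 adjusted over the list alone), camera adjusted p = 8.11e-05 and adjusted p = 0.144 with an estimated correlation. Chemokines and inflammatory mediators (median 0.26, 0 of 31 called, 3 adjusted over the list alone, camera adjusted p = 2.37e-05), osteoclast markers (0.23, 1 of 19, 6 adjusted over the list alone, 2.37e-05), M1-type activation (0.28, 1 of 26, 4 adjusted over the list alone, 8.11e-05) and macrophage identity (0.06, 1 of 29, 4 adjusted over the list alone, 0.00146) had adjusted p = 0.0982 with an estimated correlation. Tumour-associated macrophage markers had a median of 0.21 with 2 of 34 called (9 higher and 4 lower adjusted over the list alone), camera adjusted p = 0.00426 and adjusted p = 0.357 with an estimated correlation. Its called genes were Folr2 (1.13), not called without WT macrophage 1, 2 or 3 or KO macrophage 1 or 3 (adjusted p up to 0.0842), and Gpnmb (1.03), not called without WT macrophage 2 or KO macrophage 3 (up to 0.0552). NRF2 targets (0.16, 0 of 27 called, 1 adjusted over the list alone, camera adjusted p = 0.0318) and dendritic cell markers (0.09, 1 of 20, 2 adjusted over the list alone, 0.0318) had adjusted p = 0.644 and 0.13 with an estimated correlation. List calls were lost for NRF2 targets without WT macrophage 2 (adjusted p = 0.0618), WT TAM 1 (0.41), WT TAM 3 (0.305), KO macrophage 3 (0.0545) or KO TAM 2 (0.204), for dendritic cell markers without WT macrophage 2 (0.0586), WT TAM 1 (0.0548), WT TAM 2 (0.0686), KO macrophage 2 (0.052) or KO TAM 2 (0.108) and for tumour-associated macrophage markers without KO TAM 1 (0.102).

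Proliferation genes had a lower response in KO, with a median of -0.61 and 0 of 43 called (3 lower adjusted over the list alone), camera adjusted p = 8.47e-12 and adjusted p = 0.37 with an estimated correlation. Glycolysis and hypoxia genes did too, with a median of -0.18 and 1 of 34 called (6 lower adjusted over the list alone), camera adjusted p = 0.0128 and adjusted p = 0.357 with an estimated correlation, a call lost without WT TAM 2 (adjusted p = 0.21) or KO TAM 3 (0.0581). At an unadjusted p under 0.05, 2130 genes passed for the interaction.

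The interaction count depended on single arrays. It was 21, 15 and 18 without WT macrophage 1, 2 and 3, 27, 247 and 25 without WT TAM 1, 2 and 3, 16, 24 and 14 without KO macrophage 1, 2 and 3, and 444 without KO TAM 1. It was 1496 without WT TAM 2 and KO TAM 1, 761 with array weights, 99 with trend and robust, 65 without dim genes, 26 with the replicate number as a block and 86 with the stromal marker mean as a covariate. Genes with a higher value in KO made up 53.5% of the main count. Without single arrays this share ranged from 38.9% (without WT TAM 2) to 72.2% (without WT macrophage 3). List calls were gained without WT TAM 2 for fatty acid synthesis (0.00232), cholesterol synthesis (0.0014), PPAR and LXR targets (0.00618), B cell markers (0.0232) and neutrophil markers (0.00947), without KO TAM 1 for fatty acid synthesis (0.0345), B cell markers (0.00798) and ER stress (0.00464), without KO macrophage 1 for B cell markers (0.0472) and without KO TAM 3 for stromal markers (0.00894). Over the 18 alternatives of each called list the p with an estimated correlation was the highest, except for interferon (0.447 with fry), and the lowest lay between 5.61e-29 (proliferation) and 0.0138 (dendritic cell markers).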

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

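The tests of stromal cells, sex, dividing stromal cells, myeloma RNA, a wrong label and a larger co-culture response were chosen only after the results were seen, and the counts over other splits of the arrays were planned.

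Stromal transcripts were lower on the KO macrophage arrays, with Bgn at 7.97 to 8.29 against 11.84 to 12.04 on WT arrays, Acta2 at 6.74 to 7.03 against 9.68 to 10.02 and Col1a2 at 5.64 to 5.77 against 8.32 to 8.60. The 11 endothelial genes had a median of 0.03 where the 14 stromal genes had -1.49, which does not speak against stromal cells alone. More stromal cells in the WT cultures cannot be told apart from macrophages that express these genes. The 14 stromal markers deviated together between arrays of a group (mean correlation 0.47, against a 95th percentile of 0.11 over 1000 random gene sets), but TAM arrays carried this (0.52, against 0.13), and the macrophage arrays, which hardly differed within groups, gave 0.1 against 0.13. Of the 28 markers of that list, 6 are also held by another list, and no sort or gate that would remove such cells is given in the sources used here. The sex of the cells cannot be told apart from the genotype, because Uty, Eif2s3y and Kdm5d were high on all 6 KO arrays (Uty 6.57 higher in KO macrophages) and low on all WT arrays, and an effect of Cd36 itself stays open.

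Of 43 proliferation genes, 38 were called lower in KO macrophages and 42 in KO TAMs, while neither list call held with an estimated correlation between genes (adjusted p = 0.147 and 0.104). Between macrophages, which were cultured without myeloma cells, the median difference was -1.18. RNA of myeloma cells is excluded there by the design and not by a test. Arrays without myeloma cells cannot speak to the difference between KO and WT TAMs. Dividing stromal cells could raise these genes in WT cultures, but the means of proliferation and stromal genes, as deviations from their group means over 12 arrays, had r = -0.13 (permutation p = 0.774) and rho = -0.07 (permutation p = 0.789), with r = -0.13 again without KO TAM 3 and WT TAM 2, which decides nothing. Sex cannot be told apart from the genotype here either (Uty 6.57), and an effect of the genotype was not tested apart from it.

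KO TAM 1 lay apart from KO TAM 2 and 3, with 550 genes more than 1 (log2) from their mean, against 113 between KO TAM 2 and 3. WT TAM 2 likewise lay apart from WT TAM 1 and 3, with 414 genes. Its median level over the plasma cell list was 6.49, against 5.82 on WT TAM 1 and 5.69 on WT TAM 3. On WT TAM 2, Jchain, Mzb1, Pou2af1 and Tnfrsf17 read 3.54, 5.44, 4.51 and 3.70. They read 3.48, 5.46, 4.53 and 3.42 on WT TAM 1 and 3.75, 5.16, 4.27 and 3.56 on WT TAM 3. Whether RNA of myeloma cells or another cause set WT TAM 2 apart was not tested. A wrong label on an array of WT cells is argued against by Cd36, which on KO TAM 1 differed by -3.65 from the lowest WT array. The plasma cell list gave no sign of RNA of myeloma cells on KO TAM 1. Its median difference from KO TAM 2 and 3 was 0.04, with a highest difference of 0.09 among Jchain, Mzb1, Pou2af1 and Tnfrsf17. However, no array held myeloma cells alone, and the list members Ighm and Fcrl5 read high in macrophages cultured without them. Whether the list would read RNA of these myeloma cells is therefore not known, and the explanation stays open. A larger response to co-culture on KO TAM 1 may account for it, since its difference from KO TAM 2 and 3 followed the WT co-culture difference across genes (r = 0.53, rho = 0.33, genes not being independent replicates). That correlation cannot tell a larger response from another difference shared with WT TAM 1 and 3, which enter the WT co-culture difference. On the third principal component KO TAM 1 (-11.29) lay with WT TAM 1 (-17.31) and WT TAM 3 (-12.66). WT TAM 2 (30.84), KO TAM 2 (13.43) and KO TAM 3 (13.62) lay on the other side. What would make the response larger was not tested.

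The genotypes differed in their response to co-culture, tested as an interaction, for these genes among the largest differences, with positive values where KO was higher. They were H2-M2 (2.72), Shisa3 (2.28), Uchl1 (2.08), Clec4a4 (1.99), Gpr141 (1.83), Spn (1.61), Cmklr1 (1.51), Gfra2 (1.34), Ddit4 (-1.49), Sema7a (-1.47), St8sia6 (-1.36), Rapsn (-1.35), Mr1 (-1.18), Tgm2 (-1.17), Bcl2 (-1.11) and Slc6a8 (-1.08). H2-M2, Shisa3, Uchl1, Clec4a4, Cmklr1, St8sia6 and Mr1 kept their call without each array in turn. For H2-M2 and Shisa3 the low level in KO macrophages left too little room above the background for a fall as in WT. The others were not called without single arrays, with a highest adjusted p of 0.135 for Gpr141 (9 of 12 arrays) and Ddit4 (9), 0.0558 for Spn (4), 0.147 for Gfra2 (8) and Rapsn (9), 0.132 for Sema7a (8), 0.0976 for Tgm2 (8), 0.0552 for Bcl2 (4) and 0.131 for Slc6a8 (9).

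The median interaction of gene lists was 0.53 for type I interferon, 0.34 for MHC class II, 0.29 for MHC class I, 0.28 for M1-type activation, 0.26 for chemokines and inflammatory mediators, 0.23 for osteoclast markers, 0.21 for tumour-associated macrophage markers, 0.16 for NRF2 targets, 0.09 for dendritic cell markers, 0.06 for macrophage identity, -0.18 for glycolysis and -0.61 for proliferation. None of these 12 list calls held with an estimated correlation (adjusted p from 0.0982 to 0.644), and 0 to 2 genes of each list were called.

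For the interaction, the counts over other splits give no level for chance. Its 43 genes were matched or passed by 5 of 100 drawn splits of the arrays, the real one included, and the highest other count was 1874. All 5 kept the macrophage arrays of each genotype together, so that those which mixed the TAM arrays carried the genotype difference of macrophages into the count. Splits that mixed the macrophage arrays gave at most 10 genes, but that difference then adds to their spread. Whether chance is excluded was therefore not decided. For the other comparisons 10 splits of 6 arrays are too few for a share under 0.05, and the real split was 1 of 10 in each. The real counts were 2561 in WT cells, 1449 in KO cells and 2512 between macrophages, with a highest other count of 0 for each, and 2710 between TAMs, with a highest other count of 794. That split put WT TAM 1, WT TAM 3 and KO TAM 1 together. Every other split mixes the real groups, so their difference adds to the spread. The low counts of those splits are therefore no support for the real grouping.

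Among 17824 probe sets without a single gene symbol, which enter none of the main comparisons, 119 were higher and 251 lower in WT TAMs than in WT macrophages, and 88 were higher and 161 lower in KO TAMs than in KO macrophages.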

How the results depend on the processing

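Leaving out WT TAM 2 and KO TAM 1 and the stromal covariate were chosen only after the results were seen. Called lists and called named genes kept their direction, except with that covariate, while some lists and named genes that were not called turned. The majority of called genes turned with quantile normalization and with centring in WT cells and between macrophages. Between TAMs it turned with quantile normalization only. In KO cells and for the interaction it did not turn with either. The cause of each change was not tested unless given. The 64 called lists kept their call in 34 cases with the covariate, 57 without dim genes, 56 without WT TAM 2 and KO TAM 1, 46 with fry, 2 with an estimated correlation and 61 with both scalings. Of 445 named gene calls, the 2 of Cd36 not counted, 439 held with array weights, 439 with probe sets averaged, 430 centred, 429 quantile-normalized, 419 with trend and robust, 429 without both arrays and 168 with the covariate. Without dim genes 444 of 444 held and with the 6 arrays compared 298 of 423. Falls of faint genes are limited by the background, near 3.05 to 4.10 for Uty, Eif2s3y and Kdm5d on WT arrays.

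In the order WT TAM, KO TAM, macrophage and TAM genotype comparisons and interaction, the main counts were 2561, 1449, 2512, 2710 and 43. A minimum of 2-fold left 511, 290, 463 and 633 by its construction. Array weights gave 3976, 2705, 4923, 4725 and 761. Without WT TAM 2 and KO TAM 1 there were 4049, 4558 and 4480 in WT cells, macrophages and TAMs and 1496 for the interaction, with r = 0.456 between co-culture effects. With the 6 arrays compared, counts were 505 in KO cells, 4716 in macrophages and 638 in TAMs. For the interaction, 65 genes passed without dim genes and 99 with trend and robust. Leaving out each array in turn, which also leaves fewer arrays, gave 1475 to 2671, 611 to 1659, 1403 to 1503, 1749 to 3710 and 14 to 444 genes, 199 to 535 higher and 216 to 547 lower in both, and r = 0.532 to 0.715. The called lists numbered 0, 1, 0, 1 and 0 with an estimated correlation, and 4 with fry for the interaction.

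The covariate follows genotype and culture and so takes up part of both. With it, 1142, 193, 190, 526 and 86 genes and, in macrophages and TAMs, 8 and 9 lists were called. Directions reversed for Csf1 (0.022), Ebf1 (0.68) and Plin2 (0.31) between macrophages and for Pdk4 (0.19), Nqo1 (0.033), Ebf1 (0.029) and Ctsk (0.037) between TAMs, and for glycolysis in KO cells (adjusted p = 0.762) and macrophages (0.785) and matrix genes in macrophages (0.94).

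Samples share replicate numbers. Of 18 same-number pairs, 2 deviated together above 0.1 (-0.06 to 0.27) and 5 matched best with their own number. Those 2 were pairs of a WT TAM and a KO TAM array. Numbers 1, 2 and 3 gave 0.27, 0.25 and 0.03 there, each above the highest with another number (-0.13, 0.07 and 0.01). A pairing of TAM arrays by number is therefore not excluded. Macrophage arrays varied little within groups, so their pairs say little. The replicate block gave 2423, 1326, 2311 and 2564 genes and 26 for the interaction, and kept all 64 lists and 418 of 445 named gene calls.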

Other observations

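Several gene groups showed no list call in any comparison. Cholesterol synthesis genes (18 measured, 0 called in each comparison, 0 adjusted over the list alone) had camera adjusted p = 0.893 in WT TAMs, 0.662 in KO TAMs, 0.157 between macrophages, 0.256 between TAMs and 0.776 for the interaction. Yet their mean varied widely among TAM arrays, at 9.40, 7.33 and 9.13 on WT TAM 1, 2 and 3 and 9.24, 7.61 and 8.22 on KO TAM 1, 2 and 3, against 8.58 to 8.66 on WT and 8.31 to 8.36 on KO macrophage arrays. Fatty acid synthesis genes rose in 3 of 21 cases in WT TAMs (3 adjusted over the list alone, camera adjusted p = 0.636) and 1 of 21 in KO TAMs (1 adjusted over the list alone, 0.54). M2-type activation genes rose in 3 and fell in 2 of 27 cases in WT TAMs (3 and 2 adjusted over the list alone, 0.181), and between TAMs their median of 0.02 and mean of -0.08 differed in sign (0.605).

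The lists of T and NK cell, neutrophil, mast cell and erythroid markers did not pass either. In WT and KO TAMs against macrophages, T and NK cell markers rose in 1 of 22 cases each (1 and 1 adjusted over the list alone, camera adjusted p = 0.893 and 0.448), with a median of -0.04 and a mean of 0.11 in WT. Neutrophil markers fell in 2 and 0 of 24 cases (2 and 0 adjusted over the list alone, 0.636 and 0.331), and mast cell, basophil and eosinophil markers fell in 1 of 19 each and rose in 0 and 1 (the same numbers adjusted over the list alone, 0.322 and 0.999). Erythroid and megakaryocyte markers rose in 2 and 1 and fell in 2 and 1 of 12 (3 and 1 up and 2 and 1 down adjusted over the list alone, 0.636 and 0.506). The mean of the T and NK markers lay between 4.57 and 4.79 on the 12 arrays.

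Some genes, chosen after their values were seen, had high levels in macrophages and varied among TAM arrays. Of 16 B cell markers, 4 fell and 0 rose in WT TAMs and 1 fell and 0 rose in KO TAMs (4 down in WT and 1 up and 4 down in KO adjusted over the list alone). Whether the cultures held B cells was not tested. Ighm, the immunoglobulin mu heavy chain, read 9.53 to 9.75 on WT and 11.61 to 11.68 on KO macrophage arrays, 5.30 to 6.25 on WT TAM arrays, and 6.57, 10.25 and 9.44 on KO TAM 1, 2 and 3. Fcrl5, an Fc receptor-like protein, read 9.94 to 10.22 and 10.65 to 10.75 on WT and KO macrophage arrays, 4.64, 7.19 and 5.24 on WT TAM 1, 2 and 3 and 5.41, 9.95 and 10.18 on KO TAM 1, 2 and 3. The scavenger receptor Marco had a like order, with 11.92 to 12.10 on the 6 macrophage arrays, 8.20, 11.36 and 9.14 on WT TAM 1, 2 and 3 and 8.70, 11.93 and 11.97 on KO TAM 1, 2 and 3. Tnf read 10.42, 9.49 and 10.28 on the WT TAM arrays and 8.51, 10.64 and 11.09 on the KO TAM arrays in the same order.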
